A study of Mus musculus with 73 samples.

How the data were processed

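Single cells were sorted as macrophages from the right lung lobes of 1 adult mouse of 10 weeks, 7 days after surgical removal of the left lung. The mouse carried green fluorescent protein under control of Csf1r, and the labels give the sort as CD45-positive, CSF1R-GFP-positive and F4/80-positive, with Ly6G named without a sign. Cells were captured on a microfluidic chip (Fluidigm C1), polyadenylated RNA was amplified with the SMARTer chemistry and libraries were made with Nextera XT, per the labels' protocols. All 73 cells belonged to 1 group, and each column was matched to its sample through the cell number in the sample's title, with 0 columns left over.

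Per the submitters' processing notes, the tools were CASAVA 1.8, TopHat2 2.1.0, Cufflinks 2.2.1 and Cuffnorm, with the genome build mm10. The gene annotation and any filter on cells were not given in the sources used here. The deposited FPKM table holds fragments per kilobase of transcript, normalised per cell by the authors' tools. Sums of mouse FPKM per cell ran from 168983 to 691698. The deposited count table holds a signal, fragment counts that the authors' tools had divided by a factor per cell, and not raw counts. Of 100696 values between 0.5 and 20 steps of their cell, 99.6% lay within 0.1 of a whole step, so fragments per cell were estimated by dividing by that step. Very small values left by the transcript model did not follow the steps, and no count model was fitted.

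Rows for 92 ERCC spike-ins were 0 in every cell, and 1 of 8 rows of another spike-in series held values. These rows were taken out, which left 23994 gene rows. A gene was called detected at FPKM of 1 or more, and cells needed 1000 detected genes, a filter that removed none of the 73 cells. No doublet caller was run, because each capture site on the chip is meant to hold a single cell and the number of cells is small.

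For clustering, the 1000 genes with the highest residual of the squared coefficient of variation on the mean were taken among those detected in at least 8 cells. The 190 genes of the functional lists that were not also cell type markers were left out of the clustering, so that their levels could be compared between clusters. Values were log2(FPKM + 1), scaled per gene and reduced to 10 principal components. Ward clustering was cut into 2 to 6 clusters, and the cut with the highest mean silhouette among those with at least 5 cells in every cluster was taken. A cluster was named "X-like" where at least 3 of its 10 leading genes were markers of that cell type, in 19 marker lists fixed in advance.

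A list level was the mean of log2(FPKM + 1) over the list's genes in a cell. Differences of cluster medians were set beside 10000 random lists of the same size matched on mean expression, and a difference outside the middle 95% of these is described as outside the range of random lists. This describes these cells and is not a test. Since all cells came from 1 mouse, cells are not replicates, and no p-value was computed. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only. For a count of 0, the text gives instead the share that 3 cells of the total would make. Joint detection was examined for 23 gene pairs, with the number expected if both genes were detected independently. A pair was called more or less frequent than expected where the expected share lay outside the interval of the observed one.

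The genes named in the text are members of the fixed lists, the 15 genes with the highest mean FPKM outside mitochondrial and ribosomal genes, the 15 with the highest residual variability, and for each cluster the 10 with the largest difference in mean log2(FPKM + 1) among genes detected in at least 50% of its cells. The lists, the clustering and most alternatives were fixed before the data were examined. Settings fixed in advance were other detection thresholds, the count table, other cell filters, numbers of variable genes and of components, a pseudocount of 0.1, no filter on low genes, k-means and other numbers of clusters. Added after the data were seen were rescaling the mouse FPKM to one total per cell, thinning every cell to 347003 mouse fragments with FPKM divided by the share of fragments kept, the same thinning with FPKM left unscaled, leaving out cells with endothelial markers, and a cut into 5 clusters without a minimum size.

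The clustering was tested on simulated data made from the 6151 genes detected in at least 8 cells, each shuffled over cells, with 200 genes raised in 12 cells. With a rise of 4 log2 units the adjusted Rand index of the 2-cluster cut had a median of 1 over 10 draws, with 2 units 0.800 and with 1 unit 0.0252. With no rise the median was -0.0195. The rise was applied to every value, undetected ones included, and shuffling removed differences in depth between cells. These rates need not hold for the measured values. The list comparison was tested separately on 13183 genes, each also shuffled over cells, which removes the correlation between genes. Among 200 random lists with no effect, 10 fell outside the middle 95%, and all 200 lists raised by 2 units lay above it. The first rate need not hold for the measured values, in which genes are correlated. Undetected values were raised here as well, so the second rate need not hold either. The rise of 2 units exceeds every difference found outside that range between the named clusters, except lipid handling. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and scikit-learn 1.9.0, and figures used matplotlib 3.10.9. Gene positions were taken from the GENCODE M21 annotation of the same build.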

Results

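The series measured the transcriptomes of 73 individual cells, sorted as lung macrophages, from 1 mouse, 7 days after pneumonectomy, an operation after which the remaining lung lobes grow. Cells from an unoperated lung were not analysed here, so the values describe the cells of the regenerating lung and no change caused by the operation. The comparisons were made among the cells. The median cell held an estimated 2258330 fragments, with a range from 902485 to 4305008. Of these, 347003 to 3485945 per cell came from mouse genes, and the remainder from a spike-in RNA. A median of 2290 genes was detected per cell (interquartile range 1996 to 2701, range 1044 to 3745). At least 1 cell held each of 11868 genes, and 74 genes were found in every cell.

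**Figure D1:**
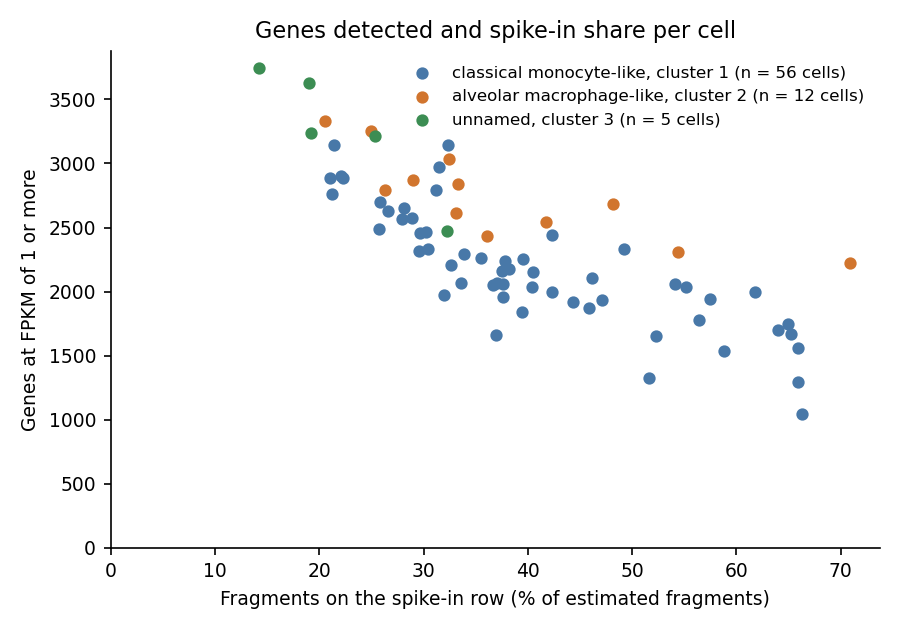
Genes at FPKM of 1 or more (vertical axis) against the share of estimated fragments on the spike-in row in percent (horizontal axis), with 1 point per cell coloured by cluster. Spike-in shares ran from 14.2% to 70.9%, and the cell with the most genes, 3745, had the lowest spike-in share.

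The most abundant transcripts were those of cytoskeletal, iron-storage and myeloid genes. Actb led with a mean FPKM of 12731.5 ± 8411 (SD over 73 cells), followed by Tmsb4x, the actin-binding thymosin, at 11486 ± 5707, and by Lyz2, the macrophage lysozyme, at 8688 ± 5929. Ferritin light chain Ftl1 and heavy chain Fth1 had means of 8133 and 8081. Tyrobp and Fcer1g, adaptors of activating myeloid receptors, reached 2638 and 1868 and were detected in 72 cells each.

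Transcripts of the genes behind the sort were found in most cells, but not in all. Ptprc, which encodes CD45, was detected in 69 of 73 cells (94.5%, 95% interval 86.6 to 98.5). Csf1r, the receptor of macrophage colony-stimulating factor, was detected in 65 cells (89.04%, 79.5 to 95.1). Emr1, now called Adgre1 and encoding F4/80, was detected in 41 cells (56.2%, 44.1 to 67.8). All 3 were found together in 37 cells (50.7%, 38.7 to 62.6). Cd68 and Lyz2 were detected in 71 and 72 cells, and Itgam, the integrin chain CD11b, in 43. In mm10, Csf1r lies on chromosome 18 from 61100598 to 61132149, Ptprc on chromosome 1 from 138062861 to 138175708 and Emr1 on chromosome 17 from 57358691 to 57483527, all annotated as protein-coding. Detection of all 3 genes together depended on the threshold, at 34.2% of cells for FPKM of 10 or more and 67.1% for any value above 0.

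Clustering addressed whether the sorted cells formed distinct populations. A group of 12 cells stood apart with markers of alveolar macrophages, the resident phagocytes of the air spaces. Its leading genes included Ear2, Plet1, Atp6v0d2, Car4, Chil3 and Ear1, all from the alveolar macrophage list, and also Cd9, 1100001G20Rik, Ltc4s and Lpl. Ear2 and Chil3 were detected in 12 of 12 of these cells, and Car4 in 10. Ear2 is also on the non-classical and Chil3 on the classical monocyte list, and they were detected in 16 and 36 of the 61 other cells. Siglec5, also on the alveolar macrophage list, was detected in 4 of the 12 after thinning to one depth. The 12 cells made up 16.4% of the total (95% interval 8.79 to 26.95). Their median level over the 12 alveolar macrophage markers was 6.92 on the log2(FPKM + 1) scale, against 0.80 in the largest cluster. Markers such as Ear2, Car4 and Chil3 entered the clustering and gave the group its name, so this gap was in part fixed by that choice. Chil3, a chitinase-like secreted protein, lies on chromosome 3 from 106147554 to 106167564.

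The largest cluster held 56 cells (76.7%, 65.4 to 85.8) and was led by Ifitm3, Ifitm2, Plac8, Ly6c2, Fyb, S100a6, Cd52 and S100a4. Of these, Plac8, Ly6c2 and S100a4 were among the classical monocyte markers, and the cluster is called classical-monocyte-like. Ccr2, the receptor that draws monocytes into tissue (chromosome 9, 124101950 to 124113557), was detected in 45 of the 56 cells. It was detected in 0 of the 12 alveolar-macrophage-like cells, a count that allows a share of up to 25% (3 of 12 cells) with a detected transcript and sets no limit on cells whose transcripts were missed. The cluster was mixed. Of its 56 cells, 41 held at least 7 of the 10 classical monocyte markers, 15 held 5 or fewer and 0 held 6, a division made after the values were seen. The share of 76.7% is therefore not a share of monocytes.

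**Figure D2:**
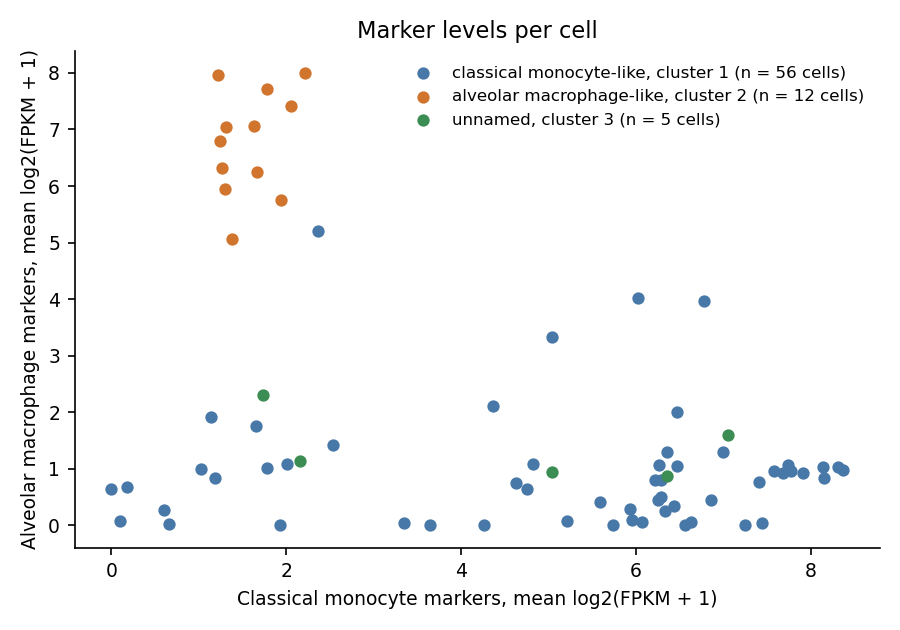
Mean log2(FPKM + 1) over the alveolar macrophage markers (vertical axis) and over the classical monocyte markers (horizontal axis), with 1 point per cell coloured by cluster. The 12 alveolar-macrophage-like cells lie at 5.06 or higher on the vertical axis, and 1 cell of the classical-monocyte-like cluster reaches 5.20. Markers on both axes could enter the clustering and were used to name the clusters.

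A further 5 cells formed an unnamed cluster, 6.85% of the total (2.26 to 15.3). It was led by the class II genes H2-Aa, H2-Ab1, Cd74 and H2-Eb1, by the cell cycle genes Stmn1, Cdca8 and Rrm2, and by Mgl2. Ccr2 was detected in 5 of 5 of these cells. Median depth was highest in the unnamed cluster, at 3219620 mouse fragments against 1386820 in the classical-monocyte-like and 1057400 in the alveolar-macrophage-like cluster. Median genes detected were 3238, 2132.5 and 2739.5 in that order. Among the unnamed cells, cells 42 and 84 were shallower, at 1634968 and 2209122 mouse fragments.

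The support for the number of clusters was limited. The mean silhouette of the cut into 3 was 0.257. Among 100 data sets in which each gene was shuffled over cells, 80 gave a cut under the same rule, with a median silhouette of 0.0891 and a highest of 0.275, above the observed value. Without the minimum cluster size, the highest shuffled silhouette was 0.482. Most other settings gave 2 clusters, with the 5 unnamed cells merged into the largest. With no filter on low genes, the rule gave no division into clusters. With every cell thinned to one depth, the rule gave 2 clusters in 12 of 20 random draws and 3 or more in 8. In the first draw the 3 clusters were the same, but the largest no longer met the rule for a name.

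Levels of the functional lists, whose genes had not entered the clustering unless they were also markers, differed between the named clusters. Among the 15 lists, 6 lay outside the range of random lists, with lipid handling, matrix remodelling, alternative activation and housekeeping higher in the alveolar-macrophage-like cells, and antigen presentation and interferon response lower. The housekeeping list was higher by 0.67, a difference in these control genes that stands beside all others. With the classes kept and cells thinned to one depth, 5 of the 6 lists remained outside the range, and antigen presentation moved inside it.

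Lipid handling showed the largest difference, 2.15 log2 units (100th percentile of random lists), and 9 of its 12 genes outside the clustering markers were higher. Lpl, lipoprotein lipase, had a mean FPKM of 334 ± 245 (SD over 12 cells) in alveolar-macrophage-like cells against 8.01 ± 20.2 (SD over 56 cells) in classical-monocyte-like cells, and was detected in 12 of 12 and 16 of 56. Plin2, a coat protein of lipid droplets, had means of 612 ± 735 and 105 ± 177. The cholesterol exporter Abcg1 had means of 471 ± 440 and 89.9 ± 188. The oxidised-lipid receptor Msr1 went the other way, detected in 2 of 12 and 29 of 56 cells. So did Apoe, a list gene left out of the level as a marker, detected in 1 of 12 and 40 of 56. Pparg and Fabp4, left out likewise, went with the list. After thinning to one depth they were detected in 10 and 7 of 12 against 3 and 6 of 56 cells.

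Matrix remodelling was higher by 0.86 in the median (98.9th percentile), but its members were divided, with 9 genes higher and 10 lower. The cathepsins Ctsd and Ctsk were higher, with means of 1033 ± 718 against 114 ± 196 and 219 ± 264 against 4.05 ± 18.9. Thbs1, thrombospondin 1, was detected in 0 of 12 alveolar-macrophage-like and 40 of 56 classical-monocyte-like cells.

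The alternative activation list is named for the programme that macrophages take up under type 2 cytokines. It was higher by 0.72 (97.8th percentile), close to the 0.67 of the housekeeping list, with 6 genes higher and 5 lower. In the unnamed cluster the list stood 0.65 above the classical-monocyte-like cluster (80.1st percentile), with 10 genes higher and 1 lower. Levels in its 5 cells ran from 0.16 in cell 37 to 4.82 in cell 42, so single cells can carry this count. Mrc1, the mannose receptor, was detected in 12 of 12 alveolar-macrophage-like cells and 16 of 56 classical-monocyte-like cells, with means of 144 ± 69.9 and 42.7 ± 103. Arg1, arginase 1, was found in 5 of the 73 cells (6.85%, 2.26 to 15.3), of which 0 were alveolar-macrophage-like. Retnla, a common marker of this state, was listed at 0 in all cells, as were the cytokines Il4, Il5 and Il13. Il4ra, the receptor chain shared by IL-4 and IL-13, was detected in 20 cells (27.4%, 17.6 to 39.1), 15 of them classical-monocyte-like. A value of 0 does not show that a gene was off, since the housekeeping gene Hprt was detected in 38 of 73 cells. The type 2 cytokine and receptor list as a whole differed by -0.06 (25.9th percentile).

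Antigen presentation was lower in the alveolar-macrophage-like cells, with a difference of -0.94 (percentile 2.01), and 10 of 11 genes were lower. At one depth the difference was -0.90 (percentile 2.97), inside the range of random lists. H2-Aa, a class II chain (chromosome 17, 34282744 to 34287823), was detected in 2 of 12 alveolar-macrophage-like cells, in 19 of 56 classical-monocyte-like cells and in 4 of the 5 unnamed cells. Within the classical-monocyte-like cluster, 7 cells set apart afterwards as interstitial-macrophage-like had a mean H2-Aa of 7143 and a mean Cd74 of 21353, against 606 and 1809 in the other 49. In the unnamed cluster this list stood 4.21 units above the classical-monocyte-like cluster, with 11 of 11 genes higher. Its 5 cells were unlike each other. The level was lowest in cell 37, at 2.12 with 11 G2/M genes at FPKM of 10 or more. It was highest in cell 42, at 9.44 with 0 such genes. Interferon response was low throughout, with medians of 0.11 and 0.40. Irf7 and Oasl2 were detected in 10 and 11 classical-monocyte-like cells and in 0 of the 12.

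**Figure D3:**
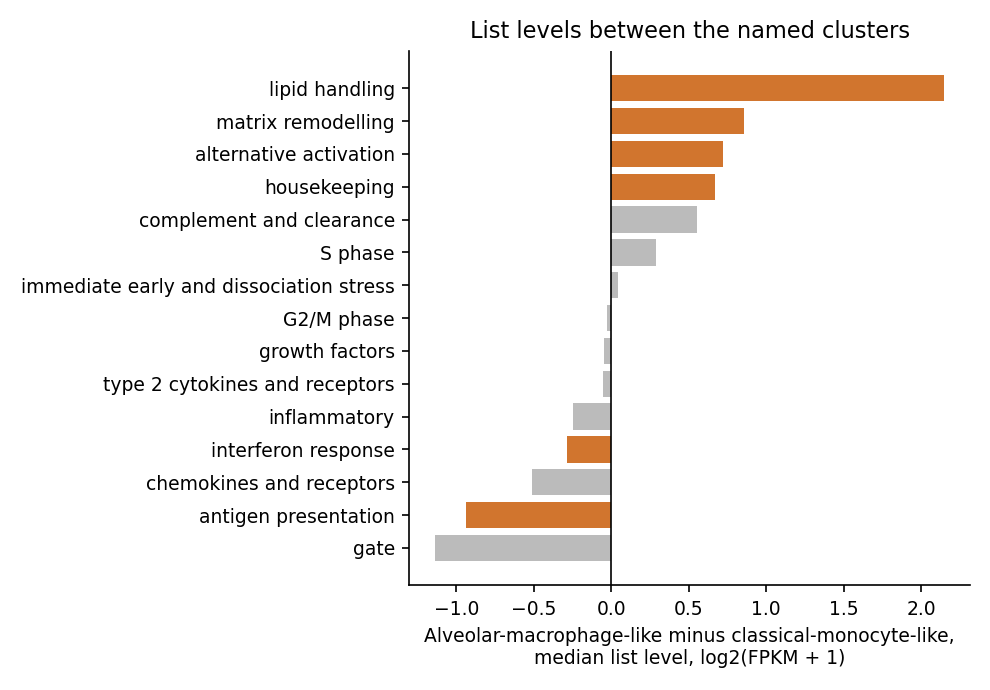
Difference of the median list level, alveolar-macrophage-like minus classical-monocyte-like, in log2(FPKM + 1), with 1 bar per list. Orange bars mark the 6 lists outside the middle 95% of random lists and grey bars the others, and lipid handling is the longest bar at 2.15.

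Inflammatory and chemokine lists did not lie outside the range of random lists between the named clusters, with differences of -0.25 and -0.51. Single members were unequal. Il1b, interleukin 1 beta, was detected in 51 of 56 classical-monocyte-like cells and 6 of 12 alveolar-macrophage-like cells, with means of 1559 ± 1493 and 195 ± 414. Il18 was detected in 15 of 56 and 12 of 12. Ccl6 had a mean of 4520 ± 3140 in alveolar-macrophage-like and 541 ± 547 in classical-monocyte-like cells, whereas Ccl9 was detected in 5 of 12 and 50 of 56. Complement and clearance genes differed by 0.55 (82.1st percentile), growth factors by -0.05 (15.6th percentile) and immediate early and stress genes by 0.04 (56.7th percentile). The latter were high in both classes, with Fos in 69 and Zfp36 in 72 of the 73 cells.

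Cell cycle transcripts were concentrated in few cells. At least 3 of the 14 G2/M genes were detected in 8 cells (10.96%, 4.85 to 20.46), 4 of them in the unnamed cluster, 2 alveolar-macrophage-like and 2 classical-monocyte-like. This count leaves out S phase genes, of which cell 50, singled out after its values were seen, held 11 of 12 with 1 G2/M gene. It lay in the classical-monocyte-like cluster, but its level over the classical monocyte markers was 0.60 against a cluster median of 6.05. At FPKM of 10 or more, 3 unnamed cells and 1 alveolar-macrophage-like cell had at least 3 such genes. Top2a, a topoisomerase of dividing cells, was detected in 4 of the 5 unnamed cells, in 3 of the 12 alveolar-macrophage-like cells and in 1 of the 56 classical-monocyte-like cells. Rrm2, which supplies deoxynucleotides for replication, was detected in 4, 0 and 2 of these cells. The share depended on the threshold and rose to 65.8% with any value above 0, so low values of these genes were spread over many cells.

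**Figure D4:**
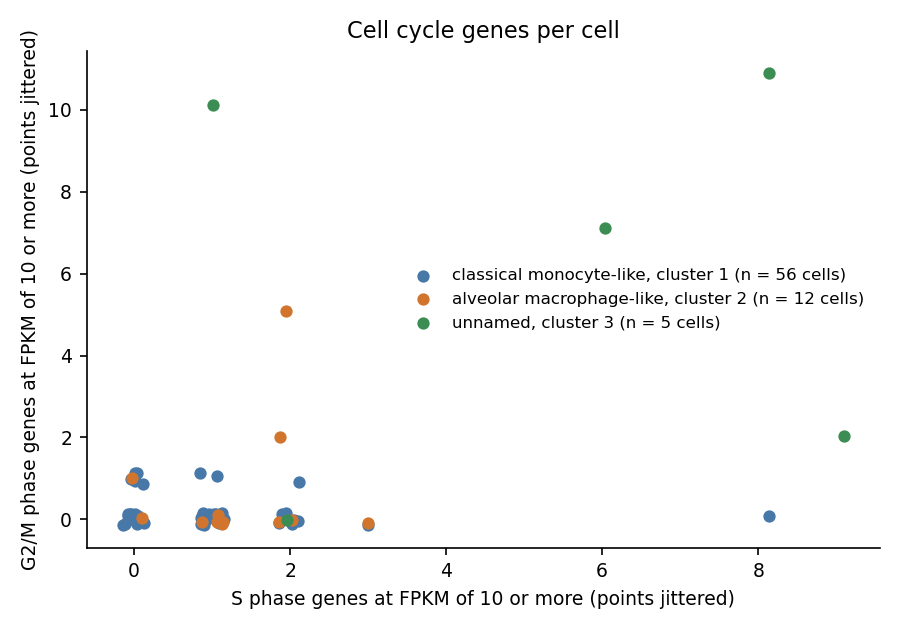
G2/M genes at FPKM of 10 or more (vertical axis, of 14) against S phase genes at FPKM of 10 or more (horizontal axis, of 12), with 1 point per cell coloured by cluster and small random offsets to part overlapping points. The highest cell, in the unnamed cluster, holds 11 G2/M and 8 S phase genes.

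Joint detection asked whether genes of different macrophage states were found in the same cells. Of the 23 pairs, 3 were found together in more cells than independence would give, and 0 in fewer. Ccr2 and Ly6c2 were detected together in 39 cells (53.4%, 41.4 to 65.2), with 28.1 expected. After thinning to one depth, each was detected in 0 of the 12 alveolar-macrophage-like cells, so pooling the clusters adds to this excess. Expected numbers within clusters were not computed. C1qa, a complement chain of interstitial macrophages, was detected in 10 cells, and Mrc1 was detected in 10 of those 10, with 4.38 expected. Mki67 and Top2a were found together in 5 cells, with 1.53 expected. With expected numbers computed separately for cells with more and with fewer genes detected, these were 28.2, 4.35 and 1.74. Il4ra and Chil3 were found together in 13 cells, with 13.2 expected, and Il4ra and Arg1 in 2 cells, with 1.37 expected. Ccr2 and Mrc1 were found together in 14 cells (19.2%, 10.9 to 30.1), with 21.9 expected, a share just inside the upper end of the interval. Pooling adds to this shortfall too, as 12 of 12 alveolar-macrophage-like cells held Mrc1 and 0 held Ccr2. With FPKM of 10 or more as the threshold, 1 pair was above expectation.

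Markers of other lineages were rare. At least 3 markers of a lineage outside the mononuclear phagocytes, at FPKM of 10 or more, were found in 4 of 73 cells (5.48%, 1.51 to 13.4). Endothelial markers accounted for cells 2, 38 and 54, and alveolar epithelial markers for cell 48. In cell 48, the surfactant gene Sftpc reached an FPKM of 464. The lymphoid, neutrophil, mast cell, erythroid and platelet lists gave 0 such cells, which allows a share of up to 4.11% (3 of 73 cells) with such detections for each.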

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

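The bounds for thinning on the 2-cluster cut and on the G2/M genes, and for rescaling, were fixed after the clusters were known but before these tests were run, the thinning itself was corrected after a first result, and the other tests were chosen afterwards. Spike-in RNA, which entered no comparison above, took a median of 36.6% of the estimated fragments per cell. The signal lay in 1 spike-in row, with values in all 73 cells. The ratio of mouse to spike-in fragments, a relative measure of RNA content if equal spike-in was added to each cell, had medians of 1.66 in the classical-monocyte-like, 2.01 in the alveolar-macrophage-like and 4.199 in the unnamed cluster.

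The first pattern weighed was the separation of 12 cells with alveolar macrophage markers. As first run, thinning to one depth left FPKM unscaled, so that deep cells also lost FPKM and mouse FPKM sums ran from 40805 to 474979; the adjusted Rand index of the 2-cluster cut was then 0.107, which met the bound set for depth as the cause. That value was seen before the error was found, and the bounds were kept when FPKM was divided by the share of fragments kept. A difference in depth between cells is argued against by the corrected index of 1, and by a range of 0.871 to 1 over 20 draws, where the bound was 0.8. Scaling of the deposited FPKM is argued against only narrowly, by an index of 0.805 against the same bound, and no biological explanation was tested, as the design has 1 group.

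The second pattern was the G2/M transcripts in the unnamed cluster. Greater depth of these cells is argued against, since 4 of the 4 cells with at least 3 G2/M genes still had them after thinning. The other 68 cells had a median of 0 G2/M genes at FPKM of 10 or more, against 7 in the unnamed cluster. This argues against free RNA shared by all cells at that level only. The bound was set when the G2/M counts per cell were already known. Free RNA at lower values stays open, as 65.8% of cells held at least 3 such genes at any value above 0. Dividing cells are a candidate explanation that was not tested, and the cluster itself merged with the largest one under most settings.

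The third pattern was transcripts of other lineages in cells 2, 38, 48 and 54, although the sort for CD45, CSF1R-GFP and F4/80 should leave out endothelial and epithelial cells. Free endothelial or epithelial RNA shared by all cells could not be decided on. The other 69 cells held medians of 0 and 0 such markers at FPKM of 10 or more. These cells were left over because each held fewer than 3 of them. The median of 3 or more set for free RNA could therefore not occur. That cell 2 holds a myeloid cell together with an endothelial one is argued against by 1 of 7 myeloid gate genes at FPKM of 10 or more, 2 of 10 classical monocyte markers, and Csf1r, Ptprc and Tyrobp at 0. Cell 2 held the endothelial markers Ramp2 at 564 and Cldn5 at 307, with Emcn and Vwf at 0. It was nevertheless counted in the classical-monocyte-like cluster. A myeloid cell together with an endothelial one met its bound in cell 38, with 5 of 7 gate genes beside Vwf at 48.4. So did a myeloid cell together with an epithelial one in cell 48, with 6 of 7 gate genes beside Sftpc at 464. This bound scored myeloid genes only, so it does not show that an epithelial cell was present. Cell 48 held Ager and Hopx at FPKM of 10 or more, but Cdh1 at 0 and Nkx2-1 at 0.55. After thinning to one depth, Hopx was detected in 22 of 73 cells, and Sftpa1, Sftpb, Sftpd and Lamp3 in 0. Cell 38 also held Csf1r at 80.5 and Tyrobp at 1560. The other cells had a median of 5 of 7 gate genes, so a single myeloid cell with free RNA would also meet the bound. The gate genes therefore cannot tell these apart in cells 38 and 48. That cell 54 holds a myeloid cell together with an endothelial one stays open, since it had 1 of 7 gate genes but 8 of the 10 classical monocyte markers and Lyz2 at 877, and no biological explanation was tested.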

How the results depend on the processing

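Rescaling, thinning with FPKM scaled or unscaled, leaving out cells with endothelial markers and the cut into 5 were chosen after the data were seen. The 3 clusters became 2 with 500 or 2000 variable genes, 5 or 20 components, a pseudocount of 0.1, k-means, the count table, at least 2000 genes per cell, rescaled FPKM or 1 fewer cluster; 4 with the list genes kept or 1 more cluster; 5 in the cut into 5; and 1 with no filter on low genes or after thinning with FPKM left unscaled, so that these last 2 settings gave no class shares. Thinning with FPKM scaled gave no classical-monocyte-like share, as that cluster had no name. Without cells with endothelial markers there were again 3 clusters, but the third was then an interstitial-macrophage-like group of 10 cells. In all other settings the alveolar-macrophage-like share stayed between 15.1% and 22.6% and the classical-monocyte-like share between 67.1% and 83.6%, and the number of lists outside the random range was between 4 and 7. Median genes detected were 3250 for any value above 0, 2945 for a count table value of 1 or more and 1535 at FPKM of 10 or more. Cells with all 3 gate genes made up 67.1%, 64.4% and 34.2% under those settings. Cells with at least 3 G2/M genes made up 65.8% above 0 and 52.1% by the count table. Cells with markers of another lineage made up 13.7% by the count table and 1.43% without cells with endothelial markers, a fall given by construction. Pairs found together more often than expected fell to 1 at FPKM of 10 or more and to 1 with rescaled FPKM, and 1 pair was found less often at FPKM of 5 or more, at FPKM of 10 or more and without cells with endothelial markers. Beyond these, the cause was not tested. The other 89 values moved by less than their interval, 1 SD or 1.5 times. Among single genes, pairs and lists, 35 values moved, 490 did not and no called difference changed sign. Dropping the filter on cells changed nothing, as it had removed no cell. Thinning with FPKM scaled left a median of 2270 genes.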

Other observations

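All values in this part were chosen after the data were seen, apart from the fixed marker lists. Within the classical-monocyte-like cluster, a cut of the same tree into 5 set apart 7 cells, numbers 11, 15, 32, 50, 65, 89 and 94, that were interstitial-macrophage-like as a group. Cell 89 was unlike the other 6, with a mean level of 7.41 over the classical monocyte markers, above the cluster's median of 6.05. The group was led by C1qb, C1qa, C1qc, Apoe, Ms4a7, Pf4, Ccl12, Cd74, Tmem176b and H2-Aa. C1qb, a chain of the complement initiator C1q, had a mean FPKM of 2941 in these cells and was detected in 6 of 7, against 3 of the 49 cells that remained in the largest cluster. Csf1r and Emr1 were detected in 7 of 7 of them, with means of 253 and 139. Ccr2 was detected in 3 of 7 and Ly6c2 in 1 of 7, against 42 and 38 of the 49. Mrc1 was detected in 6 of 7 and in 10 of 49. Ccl12, a monocyte-attracting chemokine, was detected in 5 of 7 and 3 of 49, with means of 1584 and 6.62. A cluster of the same name held 6 cells when the list genes were kept in the clustering and 10 cells when cells with endothelial markers were left out.

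Treml4 and Ace, both markers of non-classical monocytes, were detected together in 6 of the 73 cells (8.22%, 95% interval 3.08 to 17.04). Cell 38, among them, also held endothelial markers, and Ace alone reached FPKM of 80.6 and 33.02 in the endothelial-marker cells 2 and 54. The 3 C1q genes were found together in 9 cells (12.3%, 5.80 to 22.1). Csf1r was not detected in 8 cells, and neither Csf1r nor Emr1 in 5. Cxcr2, listed among the neutrophil markers, was detected in 62 of 73 cells at a mean FPKM of 8.47, and in 58 after thinning to one depth. Csf3r, on the same list, was detected in 37 cells and S100a8 in 7, while Camp, Ltf, Ngp and Retnlg were listed at 0 in all cells and S100a9 was detected in 1.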
